A study of Mus musculus with 8 samples.

How the data were processed

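RNA of mouse sciatic nerve segments was measured on 8 1-colour Affymetrix arrays, 2 in each of 4 groups (control or c-Jun mutant, cut or uncut), each array holding a pool of nerves of 4 or 6 mice. Per the labels' protocols, RNA was purified with the RiboPure kit and converted to biotin-labelled cRNA. The deposited values are log2 expression values, 1 per probe set and array, with 45101 probe sets. Per the submitters' processing notes they were made with RMA, which corrects the background, equalises the distribution between arrays and summarises probes, and with the package affy. Versions are not given in the sources used here. RMA compresses differences of dim probe sets and removes a shift common to all genes. Array medians lay between 6.59 and 6.65, and the values were used as deposited. Detection calls, scan dates and a genome build are not given in the sources used here, so the signal filter below replaced detection calls, array batches were not tested and no coordinates are given. The number of arrays limits the precision.

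Gene symbols came from the array's platform annotation, in which 34958 probe sets have 1 symbol, 932 several and 9211 none. Of those with 1 symbol 34754 were matched by gene number to a current gene table, and 0 symbols changed. Control probe sets (64), and probe sets with several symbols or none, named no gene. A probe set was kept if it lay above the median of its array on at least 2 arrays, which left 24220, of which 20953 had 1 symbol. Each gene was represented by its kept probe set with the highest mean (5357 genes had more than 1), which left 12094 of 18194 genes. Groups were taken from the sample labels.

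With R 4.3.3 and limma 3.58.1, a linear model with a mean per group was fitted to all 8 arrays, so that the groups share 1 estimate of the spread (4 residual degrees of freedom, with 3.59 prior degrees of freedom and a prior SD of 0.124 from the moderation). There were 5 contrasts: injury in control, injury in mutant, genotype in cut nerve, genotype in uncut nerve and the genotype by injury interaction. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, and adjusted p-values of genes are limma's. The model was tested on simulated data with 12094 genes, 50 of them changed at each size. For genotype in cut nerve it recovered 24%, 90%, 100% and 98% of genes changed by 0.5, 1, 2 and 3 on the log2 scale and called 15 of 11894 unchanged genes. For the interaction it recovered 8%, 74%, 98% and 98% and called 13. The simulated noise was drawn for each gene separately, without shifts that many genes of an array share. Recovery on the real arrays may therefore be lower.

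Before the data were examined, 23 gene lists, the contrasts, the alternatives and a rule for the genes named were fixed. The lists cover myelin, cholesterol synthesis, denervated Schwann cells, the Schwann lineage, trophic factors, the repair genes named by the study, the hedgehog pathway, AP-1 and immediate early genes, the cell cycle, macrophages, lipid-laden macrophages, neutrophils, lymphocytes, mast cells, fibroblasts and matrix, matrix proteases, cytokines and chemokines, the interferon response, endothelial cells, mural cells, adipocytes, skeletal muscle and red blood cells. The 22 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast. Beside it stand camera with a correlation estimated from the arrays and fry, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes. The genes named are Jun, the highest and lowest called genes of each contrast (8 each for injury in control and genotype in cut nerve, 5 each for the others), up to 4 called members of each list with the highest absolute change, and all repair genes named by the study in cut nerve. Genes named outside this rule, Csn2 and the keratins among them, were chosen after their values were seen. Overlaps of calls that share arrays were set beside the overlap of independent lists, beside 100 simulations without the second effect on the same shared arrays, and, chosen after seeing the data, beside 100 with the called differences of cut nerve placed on random genes and beside calls that divide the shared arrays, 1 of each group for either call.

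Alternatives were no filter and a filter at the 75th percentile, the mean of a gene's probe sets, probe sets as units, median centring, a further quantile normalisation, array weights, a trended and robust variance, an unmoderated statistic, at least 2-fold change, the replicate number as a block, only the 4 arrays compared, and each array left out in turn. A fit without both cut arrays of higher milk protein signal was added after seeing the data. For the closing observations 7 further lists were written after the values were seen: clock genes in 2 phases, glucocorticoid targets, muscle denervation genes, glandular epithelium, platelet and erythroid genes, and milk proteins.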

Results

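The series asks what the transcription factor c-Jun does in the Schwann cells of injured nerve. In adult mice 1 sciatic nerve was transected, and after 7 days a 10 mm piece distal to the injury and the intact nerve of the other side were collected from control mice and from mice carrying a c-Jun mutation. RNA of the whole segment was hybridised to Affymetrix mouse expression arrays, 1 array per pool. There were 4 groups of 2 arrays (control uncut, control cut, mutant uncut and mutant cut), 8 arrays in all. Each array held RNA pooled from the nerves of 4 or 6 mice, and the design text describes the pair in each group as independent samples. The sample labels name the tissue as Schwann cells (and schwannoma cells in a description field), but a nerve segment also holds fibroblasts, endothelial cells, macrophages and other cells, and every value below is of that mixture. Array medians lay between 6.59 and 6.65 on the log2 scale, and the small number of arrays limits the precision. Replicate arrays correlated with r = 0.984 to 0.989 across the 12094 genes tested, arrays of the other genotype in the same injury state with 0.977 to 0.987, and cut with uncut arrays with 0.854 to 0.894. A first principal component holding 82.5% of the variance separated cut from uncut nerve.

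Jun, the gene for c-Jun, was read first in every sample, since it is the gene the mutation targets. On its brighter probe set the log2 value was 9.64 ± 0.09 in control uncut nerve, 11.92 ± 0.06 in control cut nerve, 9.60 ± 0.02 in mutant uncut nerve and 10.59 ± 0.29 in mutant cut nerve (mean ± SD, n = 2 each). Jun rose after injury in control nerve (log2 fold change 2.28, SE 0.14, limma with Benjamini-Hochberg adjusted p = 2.6e-05) and in mutant nerve (0.99, adjusted p = 0.0015). It was lower in mutant than in control cut nerve (-1.33, SE 0.14, adjusted p = 0.0087), and between the uncut nerves the difference was -0.04. The call in cut nerve was lost without control cut replicate 1 (adjusted p = 0.0631) or replicate 2 (adjusted p = 0.0574). A second probe set gave -1.19 in cut nerve (adjusted p = 0.0586 among all probe sets). Whether either probe set lies in the altered part of the gene is not given in the sources used here, so these values check the sample labels only in part.

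In control mice, cutting the nerve lowered the genes of the myelin sheath and of the lipids it is built from. Of 18 measured myelin genes 16 fell and 2 did not pass (17 fell when adjusted over the list alone). Ncmap, a membrane protein of myelinating Schwann cells, went from 13.12 ± 0.04 to 6.14 ± 0.10 (mean ± SD, n = 2 each, log2 fold change -6.98, limma adjusted p = 1.7e-06). Others were Cdh1, the adherens junction protein E-cadherin (-5.65), Fa2h, which hydroxylates the fatty acids of myelin lipids (-5.48), and Drp2, a dystrophin-related protein of the outer myelin surface (-5.43). Of 19 measured genes of cholesterol synthesis 16 fell and 3 did not pass (18 fell when adjusted over the list alone), with Lss at -3.55, Idi1 at -3.49 and Hmgcs1, the enzyme before HMG-CoA reductase, at -2.65. Both lists were lower than other genes in the camera test (adjusted p = 9.6e-16 and 2.9e-12). They were not when the correlation within each list was estimated from these arrays (adjusted p = 0.166 and 0.201 with an estimated correlation). That setting rests on 4 residual degrees of freedom and lost 55 of 55 camera calls of all contrasts, so it does not tell the lists apart. By fry the adjusted p of both lists was 6.8e-05 and 0.00026.

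Genes of denervated Schwann cells and of nerve support rose in the same nerves. Of 11 measured markers of immature and denervated Schwann cells 8 rose, 1 fell and 2 did not pass (8 and 2 when adjusted over the list alone): the matrix protein Tnc rose by 5.55 (SE 0.17, adjusted p = 1.8e-06), the neurotrophin receptor Ngfr by 3.93, the transcription factor Sox2 by 2.71 and the growth cone protein Gap43 by 2.55. Of 15 measured trophic factors 11 rose and 2 fell, with the same counts when adjusted over the list alone. Gdnf rose by 5.23 (SE 0.21, adjusted p = 4.0e-06), the EGF receptor ligand Btc by 4.59 and Fgf5 by 4.41. Of the 10 measured genes that the study itself named as depending on c-Jun 8 rose and 1 fell (8 and 2 when adjusted over the list alone), among them Olig1, a transcription factor better known from oligodendrocytes, by 6.48, and the hedgehog ligand Shh, which rose from 9.54 ± 0.23 to 12.54 ± 0.32 (mean ± SD, n = 2 each). That list was chosen on these samples and is not independent evidence. In the camera test the adjusted p of these 3 lists was 0.0025, 0.00089 and 0.0010 in that order. Those calls were lost too (adjusted p = 0.201, 0.201 and 0.27 with an estimated correlation), while fry gave adjusted p = 0.00014, 0.00015 and 0.00043.

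Markers of the Schwann cell lineage went both ways: of 11 measured, 2 rose and 6 fell (the same counts when adjusted over the list alone), with Dhh at -2.01, Scn7a at -1.99 and Foxd3 at 1.08 (median -0.49, camera adjusted p = 0.0396, adjusted p = 0.408 with an estimated correlation). Of 10 hedgehog pathway genes 1 rose and 4 fell (1 and 6 when adjusted over the list alone, camera adjusted p = 0.0551). The riser was Shh. Ptch1 stood at -0.80, a call lost without control cut replicate 1 (adjusted p = 0.0634) or control uncut replicate 2 (adjusted p = 0.0567). Of 16 AP-1 and immediate early genes 7 rose and 1 fell (8 and 2 when adjusted over the list alone, camera adjusted p = 0.117). The stress-induced factor Atf3 rose by 3.43 and Fos by 1.54.

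Proliferation and immune cell genes rose in control cut nerve. Of 30 measured cell cycle genes 29 rose (29 also when adjusted over the list alone), with the proliferation marker Mki67 at 3.96 (SE 0.22, adjusted p = 1.4e-05), Birc5 at 3.92 and Rrm2, a subunit of ribonucleotide reductase, at 3.77. Of 22 macrophage markers 20 rose and 2 did not pass, both over all genes and adjusted over the list alone, with Cd68 at 3.57 and Mpeg1 at 3.24. Of 15 genes of lipid-laden macrophages 11 rose and 2 fell (12 and 3 when adjusted over the list alone), with Gpnmb at 4.33 and Trem2 at 2.90. Matrix proteases and their inhibitors rose in 11 of 15 cases and fell in 2 (the same when adjusted over the list alone), led by the macrophage elastase Mmp12 at 4.57 and the inhibitor Timp1 at 3.68. The camera adjusted p of these 4 lists was 9.6e-16, 8.3e-10, 0.00018 and 0.00080. None of the 4 calls held with an estimated correlation, as for every list (adjusted p = 0.166, 0.241, 0.245 and 0.166). Fry gave the 4 lists adjusted p = 0.00014, 0.00069, 0.00019 and 6.8e-05.

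Other cell types of the segment moved less evenly. Of 6 lymphocyte and natural killer genes 2 rose (2 also when adjusted over the list alone), the protease Gzmb by 6.31 and Klrd1 by 1.57 (camera adjusted p = 0.027, adjusted p = 0.21 with an estimated correlation). Of 16 fibroblast and matrix genes 8 rose and 1 fell (9 and 1 when adjusted over the list alone), with Postn at 1.66 and Col1a1 at 1.61, and of 13 cytokines and chemokines 6 rose and 1 fell (the same when adjusted over the list alone), with Ccl8 at 3.96. Their camera adjusted p of 0.0304 and 0.0396 became adjusted p = 0.27 for each with an estimated correlation. Of 8 adipocyte markers 4 fell (5 when adjusted over the list alone), with Retn at -1.98 (camera adjusted p = 0.0090, adjusted p = 0.442 with an estimated correlation, fry adjusted p = 0.096). No list call was made for neutrophil genes (2 of 6 rose, adjusted p = 0.522), mast cell genes (2 of 10 rose, median -0.03 but mean 0.12, adjusted p = 0.964), interferon response genes (2 of 13 rose, median 0.08 but mean -0.02, adjusted p = 0.964), endothelial markers (2 of 13 fell, adjusted p = 0.124) or mural cell markers (1 of 11 rose and 4 fell, adjusted p = 0.134). Adjusted over the list alone these 5 lists gave the same counts, except that 1 endothelial marker fell. Only 2 of 9 red blood cell genes were measured, too few for the list test, and neither Alas2 (-1.37, adjusted p = 0.18) nor Slc4a1 (-1.46, adjusted p = 0.10) passed.

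Skeletal muscle transcripts also rose after the cut. All 14 measured contractile genes had a positive change, and 11 passed (13 when adjusted over the list alone), with the actin-binding protein Actn3 at 1.88 and the giant sarcomere protein Ttn at 1.83 (camera adjusted p = 0.0025, adjusted p = 0.452 with an estimated correlation, fry adjusted p = 0.062). The Ttn call was lost without control cut replicate 2 (adjusted p = 0.0927) or control uncut replicate 1 (adjusted p = 0.0772). The muscle genes Ankrd1 and Myf6 were among the highest changes of all genes, at 5.84 and 5.17, beside the chloride channel regulator Clca3a2 at 6.66 and the Wnt inhibitor Wif1 at 6.43. Mean uncut values of Clca3a2 (4.23), Wif1 (3.52), Olig1 (4.71), Gdnf (4.55), Fgf5 (4.34), Birc5 (4.91) and Mmp12 (4.87) in control nerve lay below the 25th percentile of every array (4.95 to 5.01), as did Lrrtm4 in control cut nerve (3.91). Wif1 (3.73), Olig1 (4.62), Gdnf (4.62) and Fgf5 (4.72) lay below it in mutant uncut nerve too. The deposited values carry no detection calls, so differences against such levels are best read as lower bounds and their ranks as uncertain. Other genes at the low end were Ddn (-5.91), Smco3 (-5.62), the potassium channel Kcnk1 (-5.39) and Fam178b (-5.00). Across all 12094 genes tested, limma called 4879 in control nerve, 2761 higher and 2118 lower after the cut, of which 1511 changed at least 2-fold.

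The same injury was read in mutant mice, where 4348 genes were called (2192 higher, 2156 lower, 1370 of them at least 2-fold). Of 18 myelin genes 16 fell (16 also when adjusted over the list alone), Ncmap at -6.83 (SE 0.17, limma adjusted p = 2.5e-06), Drp2 at -5.43 and Cldn19, a tight junction protein of myelin, at -3.74, and 29 of 30 cell cycle genes rose (29 also when adjusted over the list alone), with Top2a at 4.02. Of 19 cholesterol synthesis genes 17 fell, of 22 macrophage markers 19 rose, and 12 of 15 genes of lipid-laden macrophages rose and 2 fell (17, 20, and 12 with 3 when adjusted over the list alone). The camera adjusted p of these 5 lists was 2.7e-13, 1.1e-19, 5.1e-13, 1.6e-10 and 3.6e-06. No call held with an estimated correlation (adjusted p = 0.221, 0.221, 0.221, 0.229 and 0.229), while fry gave adjusted p = 0.00016, 0.00016, 0.00027, 0.0011 and 0.00022. Denervation markers rose in 8 of 11 cases and fell in 1 (9 and 1 when adjusted over the list alone), with Tnc at 3.99 and Sox2 at 2.96 (camera adjusted p = 0.00043, adjusted p = 0.221 with an estimated correlation). Trophic factors rose in 8 of 15 cases and fell in 2 (the same when adjusted over the list alone), with Gdnf at 3.12 and Btc at 2.95 (camera adjusted p = 0.0077, adjusted p = 0.229 with an estimated correlation).

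Of the 10 measured genes that the study named 5 rose and 1 fell in mutant nerve (6 and 1 when adjusted over the list alone), with Olig1 at 3.86 and Shh at 1.46 (camera adjusted p = 0.0132, adjusted p = 0.348 with an estimated correlation), and again they are not independent evidence. Of 15 proteases and inhibitors 9 rose and 3 fell (the same when adjusted over the list alone, camera adjusted p = 0.0151, adjusted p = 0.221 with an estimated correlation), with Mmp12 at 3.40. The hedgehog (1 of 10 rose, 3 fell), fibroblast (8 of 16 rose, 1 fell), cytokine (5 of 13 rose, 1 fell) and adipocyte lists (4 of 8 fell) were also called (camera adjusted p = 0.0465, 0.0321, 0.0334 and 0.0064), with adjusted p = 0.229, 0.275, 0.273 and 0.385 with an estimated correlation. Adjusted over the list alone, 1 rose and 4 fell, 8 rose and 2 fell, 5 rose and 2 fell, and 7 fell, in that order. Of 13 endothelial markers 6 fell after the cut (7 when adjusted over the list alone), with Flt1 at -0.75 (camera adjusted p = 0.0049, adjusted p = 0.273 with an estimated correlation). Muscle genes rose here as well, 13 of 14 over all genes and 14 when adjusted over the list alone, with Ttn at 2.42 (camera adjusted p = 0.00010, adjusted p = 0.349 with an estimated correlation), and Ankrd1 rose by 6.24 and Myf6 by 5.47. Atp6v0d2, a proton pump subunit found in osteoclasts and macrophages, rose by 5.46. The count of called genes was 2734 without mutant cut replicate 2 and 2876 without mutant uncut replicate 2.

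Injury effects in control and mutant nerve, which share no array, correlated across genes with Pearson r = 0.909 and Spearman rho = 0.895. Genes are not independent replicates, so no p-value is given. With equal injury effects in both genotypes, 100 simulations gave a mean r of 0.956. They took the fitted effects averaged over both genotypes as true, noise included, and drew new noise for each gene separately. Shifts that many genes of an array share were left out. This r and the simulated shared counts below may therefore lie too high, and the gap to the observed values does not show a difference between genotypes. Of the genes called in control nerve 4801 of 4879 had the same sign in the mutant, and 3637 were called there with it. The shared risers numbered 1921 and the shared fallers 1716, where independent lists would share 500 and 378, and equal effects gave simulated means of 2328 and 2069. Opposite directions were called for 6 genes, where equal effects gave a simulated mean of 2.15 and at most 6.

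**Figure D1:**
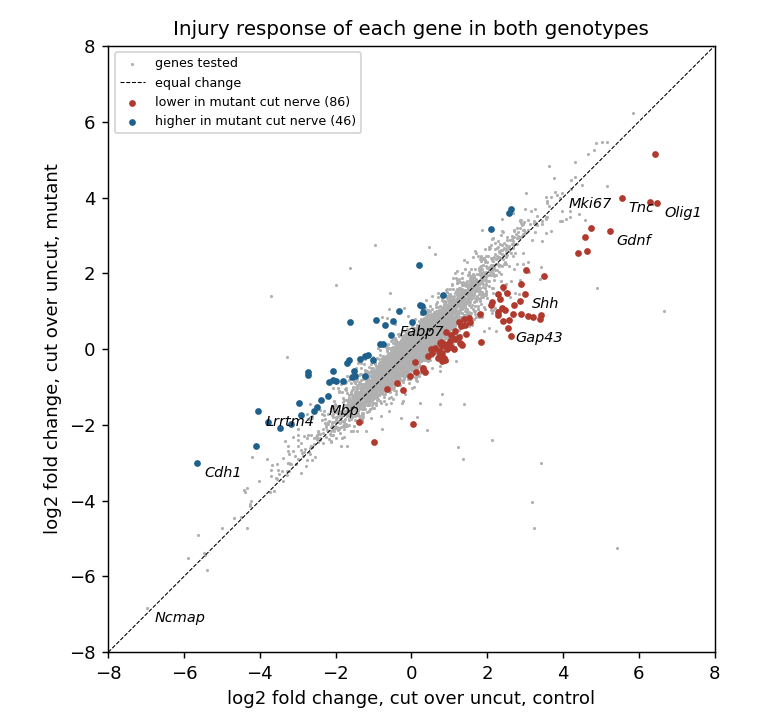
Log2 fold change after the cut in control (x axis) and mutant nerve (y axis), 1 point per gene, with the 86 genes lower and the 46 higher in mutant than in control cut nerve in colour. Olig1, at 6.48 in control and 3.86 in mutant, lies below the line of equal change and Cdh1 above it.

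The central question of the design is which genes of cut nerve depend on c-Jun. In mutant cut nerve, some trophic factors were lower than in control cut nerve. Of 15 measured trophic factors 5 were lower, none was higher and 10 did not pass: Gdnf by -2.04 (SE 0.21, adjusted p = 0.0081, 9.78 ± 0.27 in control and 7.74 ± 0.37 in mutant cut nerve, mean ± SD, n = 2 each), Btc by -1.50, Fgf5 by -1.48, Lif, a cytokine that acts on neurons, by -0.93 and Bdnf by -0.71. Adjusted over the list alone, 9 were lower and 2 higher. The list was lower than other genes (camera adjusted p = 1.4e-06, adjusted p = 0.153 with an estimated correlation), and fry found its genes lower on balance (adjusted p = 0.0205). The Gdnf call was lost without control cut replicate 1 (adjusted p = 0.0631), as was that of Btc (adjusted p = 0.0507). Fgf5 kept its call in 3 of 8 fits with 1 array left out and reached adjusted p = 0.132 without control cut replicate 1. Lif and Bdnf kept it in none of the 8, with adjusted p up to 0.231 and 0.189 without mutant cut replicate 1.

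The 10 measured genes that the study named behaved as follows. Olig1 (-2.71, SE 0.26, adjusted p = 0.0067), Gdnf, Gap43 (-2.01), Shh (-1.96), Lif and Bdnf were lower, 6 in all (8 when adjusted over the list alone). Ngfr (-0.70, adjusted p = 0.18), the adhesion proteins Cdh2 (-0.36, adjusted p = 0.53) and L1cam (-0.12, adjusted p = 0.94), and Ncam1 (0.22, adjusted p = 0.90) did not pass. Averaged over its probe sets Ncam1 stood at 0.67 (limma adjusted p = 0.069), against the direction of the list. Olig1 lost its call without control cut replicate 1 (adjusted p = 0.0507) and Gap43 without mutant cut replicate 1 (adjusted p = 0.0667). Shh lost it without control cut replicate 1 (adjusted p = 0.0874), control cut replicate 2 (0.138), either control uncut array (0.0528) or mutant cut replicate 1 (0.141). The list is not independent evidence of its direction, since the study chose it on these samples (camera adjusted p = 1.0e-11, adjusted p = 0.153 with an estimated correlation, fry adjusted p = 0.0205). Artn, also named by the study, did not pass the signal filter.

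**Figure D2:**
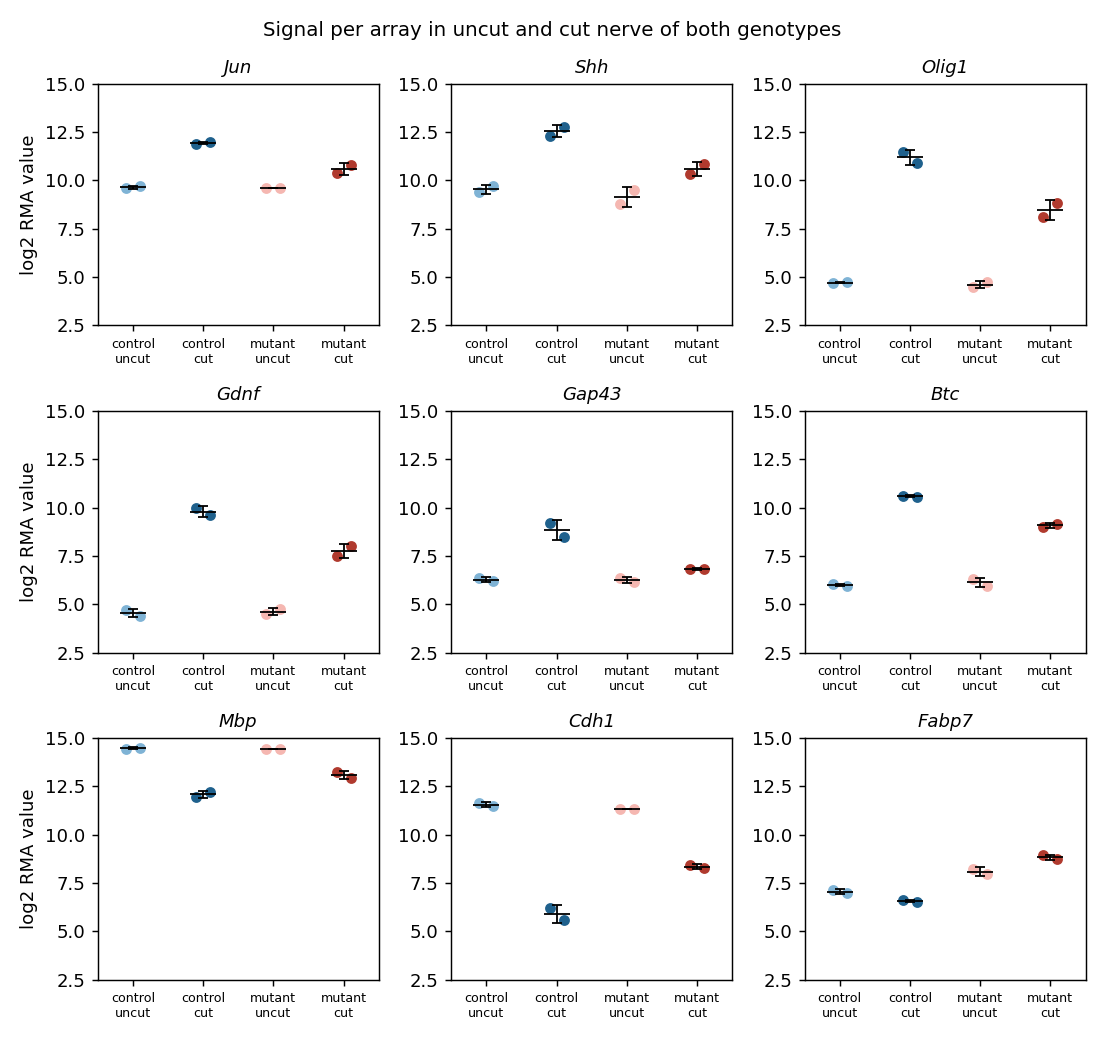
Log2 values of 9 genes, 1 point per array (n = 2 per group), with the group mean as a bar and its SD as the error bar. Gdnf averaged 9.78 in control cut nerve and 7.74 in mutant cut nerve, against 4.55 and 4.62 in the uncut nerves.

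Of 15 measured matrix proteases and inhibitors 3, all proteases, were lower and 12 did not pass (7 lower when adjusted over the list alone): the aggrecanase Adamts5 (-0.96), the plasminogen activator Plat (-0.87) and Adamts1 (-0.58). The camera adjusted p was 4.7e-06 and fry's 0.0205 (adjusted p = 0.138 with an estimated correlation). Of 11 markers of denervated Schwann cells 2 were lower, Gap43 and Tnc (-1.36), 1 was higher, the endothelin receptor Ednrb (0.92), and 8 did not pass (4 and 1 when adjusted over the list alone, camera adjusted p = 0.103). When 1 array at a time was left out, the highest adjusted p was 0.131 for Adamts5, 0.112 for Plat, 0.182 for Adamts1, 0.106 for Tnc and 0.147 for Ednrb, in that order without control cut replicate 2, mutant cut replicate 1 (Plat and Adamts1) and control cut replicate 1 (Tnc and Ednrb).

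Some genes that fell after the cut in control nerve were higher in mutant than in control cut nerve. Of 18 myelin genes 3 were higher and 15 did not pass (5 higher when adjusted over the list alone): Cdh1 by 2.44 (SE 0.20, adjusted p = 0.0040, 5.91 ± 0.46 in control and 8.35 ± 0.11 in mutant cut nerve, mean ± SD, n = 2 each), the myelin basic protein gene Mbp by 0.99 and the gap junction protein Gjb1 by 0.89. The list median was 0.09 (camera adjusted p = 0.0019, adjusted p = 0.446 with an estimated correlation), and fry made no call (adjusted p = 0.191). Mbp kept its call in 4 and Gjb1 in 5 of 8 fits with 1 array left out, with adjusted p of 0.115 and 0.112 without mutant cut replicate 1. Among 11 Schwann lineage markers Fabp7, a fatty acid binding protein of immature glia, was higher by 2.26 (SE 0.14, adjusted p = 0.0020) and the other 10 did not pass (2 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.0697). In uncut nerve Fabp7 differed by 1.04 in the same direction (adjusted p = 0.26).

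Few proliferation and immune genes passed between the cut nerves. None of 30 cell cycle genes passed limma's test over all genes or adjusted over the list alone, though 29 had a positive difference, with Rrm2 at 0.71 (adjusted p = 0.32) and a list median of 0.25 (camera adjusted p = 1.4e-06, adjusted p = 0.432 with an estimated correlation). Fry made no call for the cell cycle list (adjusted p = 0.220). None of 22 macrophage markers passed either way (median -0.03, camera adjusted p = 0.447). Mylip, a regulator of the LDL receptor, was higher by 0.70 among 15 genes of lipid-laden macrophages (1 also when adjusted over the list alone, camera adjusted p = 0.0026, adjusted p = 0.442 with an estimated correlation), a call kept in none of the 8 fits with 1 array left out (adjusted p up to 0.205, without control cut replicate 1). The mural and interferon lists were called higher with no member passing (camera adjusted p = 0.0068 and 0.049, adjusted p = 0.432 for both with an estimated correlation). Fry called neither of them nor the lipid-laden macrophage list (adjusted p = 0.273 for each). Gzmb was lower by -2.25, the 1 lymphocyte gene of 6 to pass (1 also when adjusted over the list alone, camera adjusted p = 0.0963), and its call was lost without any of the 4 control arrays (adjusted p up to 0.132, without control cut replicate 1). Of 16 AP-1 and immediate early genes, Jun and Fosl2 (-0.59) were lower and Nr4a1 (0.75) higher (3 and 2 when adjusted over the list alone, camera adjusted p = 0.501). Fosl2 kept its call in none of the 8 fits with 1 array left out and Nr4a1 in 2, with adjusted p up to 0.206 without control cut replicate 1 and 0.164 without mutant cut replicate 2. All 14 muscle genes had a positive difference and none passed (camera adjusted p = 0.0841). The camera test made no call for the cholesterol, hedgehog, neutrophil, mast cell, fibroblast, cytokine, endothelial or adipocyte lists, and among their members Shh alone passed, also when adjusted over the list alone.

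**Figure D3:**
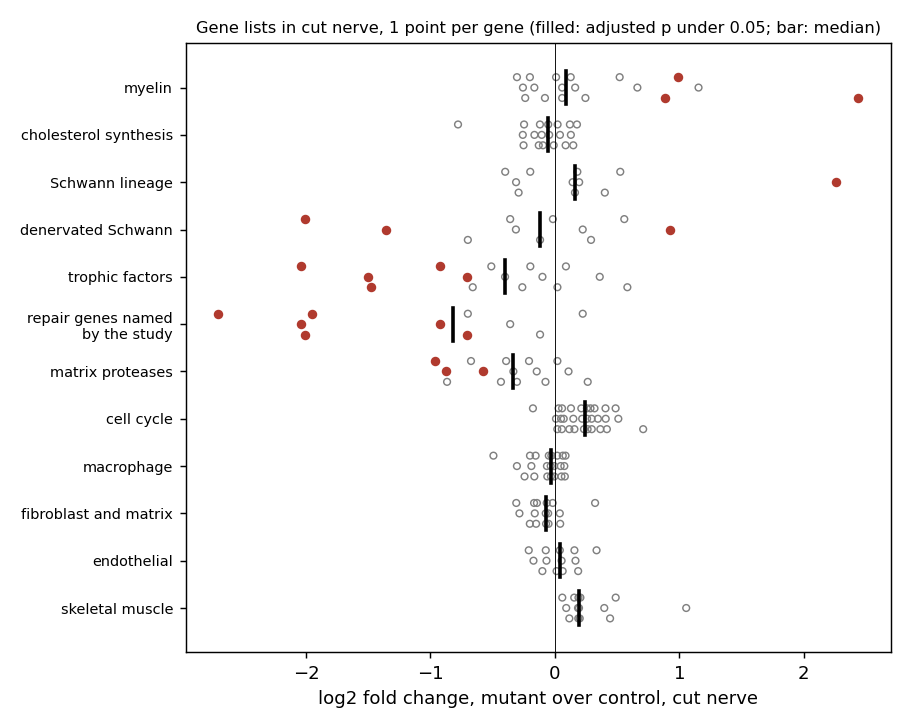
Log2 fold change of mutant over control cut nerve for the members of 12 gene lists, 1 point per gene, filled where the adjusted p over all genes was under 0.05, with the list median as a bar. The trophic factors have a median of -0.40 and the repair genes named by the study -0.82.

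Outside the lists, the genes with the highest differences were the disintegrin family member Adam23 (2.34), the leucine-rich repeat proteins Lrrtm4 (2.20) and Lrrn3 (2.03), the receptor Gpr37l1 (1.90), the inward rectifier potassium channel Kcnj10 (1.90) and the secreted antagonist Sostdc1 (1.80). The lowest were Igfbp2 (-2.60), the G protein signalling regulator Rgs8 (-2.37), the sulfotransferase Chst8 (-2.24) and the Wnt antagonist Frzb (-2.01). Of the 8 fits with 1 array left out, Gpr37l1 and Chst8 kept their call in 6, and Sostdc1, Igfbp2 and Frzb in only 3. Without control cut replicate 1 Igfbp2 stood at -3.02 and Sostdc1 at 2.02, and without mutant cut replicate 1 at -2.08 and 1.38. In all, limma called 132 of 12094 genes between the cut nerves, 46 higher and 86 lower in the mutant, 67 of them at least 2-fold. When each array was left out in turn, 11 of the 132 were called every time, among them Cdh1, Adam23, Fabp7, Lrrtm4, Lrrn3, Kcnj10 and Rgs8. The count was 13 without control cut replicate 1, 50 without control cut replicate 2, 31 without mutant cut replicate 1, 84 without mutant cut replicate 2 and 57 without either control uncut array. It was 31 with the 4 cut arrays alone and 0 with an unmoderated statistic. With both cut arrays of higher milk protein signal left out, a setting chosen after seeing the data, it was 55.

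Most of the genes that differed between the cut nerves had also changed after injury in control nerve, in the opposite sense. Of the 86 genes lower in the mutant 76 had risen in control nerve, where independent lists would share 19.6, and of the 46 higher genes 36 had fallen, against 8.06. With no effect of genotype hardly any gene is called, so 100 simulations gave a mean of 0.05 and 0.06 such genes and at most 2, which is no reference for genes that are called. When the called differences were instead placed on random genes of mutant cut nerve, 28.6% of the genes then called lower were among the risers of control nerve and 22.2% of those called higher among its fallers (at most 38.4% and 37.3% in 100 simulations), where 88.4% and 78.3% were observed. Both comparisons use the control cut arrays, and part of the excess may come from them. The arrays were therefore divided, after seeing the data, with injury called from 1 control cut array and genotype from the other. In one division 30 of 35 lower genes had risen and 10 of 15 higher genes had fallen, against 5.74 and 2.29 for independent lists, and in the other 5 of 5 and 6 of 8, against 0.884 and 0.931. After injury in the mutant itself, 41 of the 86 rose and 12 fell, and 21 of the 46 fell and 14 rose, against 15.6, 15.3, 8.20 and 8.34 for independent lists. Random placement, in which a lower gene tends to fall and a higher one to rise, gave shares of 4.23%, 88.1%, 3.95% and 88.9% in that order. Without an effect of genotype the simulated means were 0, 0.06, 0.01 and 0.05, again because hardly any gene is called. With the mutant cut arrays divided in the same way, 28 of 43 lower genes had risen and 21 of 41 higher genes had fallen in one division and 13 of 19 and 5 of 12 in the other, against 5.73, 6.37, 2.33 and 1.24 for independent lists. In the opposite sense, 6 of the 43 had fallen and 10 of the 41 had risen, against 6.68 and 5.47. In the other division 0 of the 19 had fallen and 7 of the 12 had risen, against 1.96 and 1.47. More of those 12 higher genes had thus risen than fallen.

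Genotypes were also compared in uncut nerve. Limma called 0 of 12094 genes between mutant and control uncut nerve, with 322 at an unadjusted p under 0.05. The count was 1 with the mean of a gene's probe sets or with probe sets as units, 4 with the replicate number as a block and 9 with only the 4 uncut arrays. Leaving out either control cut array or control uncut replicate 2 gave 2, and control uncut replicate 1 gave 1. All 13 endothelial markers were higher in the mutant, with Flt1 at 0.48 and Kdr at 0.39 and none passing (median 0.26, camera adjusted p = 2.9e-07, adjusted p = 0.533 with an estimated correlation). Mast cell genes (median 0.25), mural markers (0.19) and immediate early genes (0.16) were called higher, and myelin genes (-0.08), Schwann lineage markers (-0.16) and the genes named by the study (-0.11) lower, with no member of any of them passing over all genes. Their camera adjusted p ran from 0.0048 to 0.0359, with adjusted p of 0.562 for mast cell genes and 0.533 for the others with an estimated correlation. Fry called none of these lists (adjusted p = 0.408 for endothelial markers and 0.611 to 0.900 for the others). The test direction turned for the mural list without control uncut replicate 1 and for the Schwann lineage list without mutant uncut replicate 1. Adjusted over the list alone, Fabp7 was higher among the lineage markers (1.04) and no member of the other 6 lists passed, while in lists without a camera call Sox2 was lower (-0.56) and Adamts1 higher (0.55). Median and mean differed in sign for the muscle list (0.08 and -0.03) and the macrophage list (0.015 and -0.0013), which were not called. The epithelial keratins Krt18 and Krt8 differed by 3.15 and 2.58 (adjusted p = 0.10 for both), and transcripts of milk proteins were higher in both uncut mutant arrays (Csn2, beta-casein, 13.0 and 10.3) than in both uncut control arrays (3.50 and 4.14).

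The last comparison asks whether the response to injury itself differed between genotypes. The interaction, the change in mutant minus that in control nerve, was called for 20 genes, positive for 8 and negative for 12, all at least 2-fold. Cdh1 (2.65, SE 0.28, limma adjusted p = 0.0365), Lrrtm4 (2.40), Adam23 (2.33), Lrrn3 (2.05) and Kcnj10 (2.00) were the highest. Clca3a2 (-5.66), Krt8 (-3.24), Rgs8 (-2.51), the complement-related protein C1ql2 (-2.29) and Arg1, the arginase of the urea cycle and of macrophages (-2.21), were the lowest, and Btc (-1.64) and Adamts1 (-1.13) also passed. For Krt8 and Clca3a2 the uncut mutant arrays were high (8.51 ± 0.04 and 7.52 ± 0.23 against 5.93 ± 0.28 and 4.23 ± 0.60 in uncut control, mean ± SD, n = 2 each), and milk protein transcripts were high in them (array medians 11.6 and 8.98) as well as in control cut replicate 1 (9.85) and mutant cut replicate 2 (7.90). Jun (-1.29, adjusted p = 0.073), Olig1 (-2.62, adjusted p = 0.056), Gdnf (-2.11, adjusted p = 0.056), Gap43 (-1.99, adjusted p = 0.078) and Shh (-1.54, adjusted p = 0.32) did not pass.

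Of 15 trophic factors 1 and of 15 proteases 1 passed with a negative interaction over all genes, and 6 of each when adjusted over the list alone (medians -0.42 and -0.58, camera adjusted p = 3.8e-06 for both, adjusted p = 0.224 and 0.123 with an estimated correlation). None of the 10 genes named by the study passed the interaction test over all genes, and 6 passed as negative when adjusted over the list alone (median -0.76, camera adjusted p = 5.7e-07, adjusted p = 0.342 with an estimated correlation). By fry the adjusted p was 0.0482 for trophic factors, 0.0208 for proteases and 0.0857 for the genes named by the study. Cdh1 fell less in the mutant (from 11.35 to 8.35) than in control nerve (from 11.56 to 5.91). Of 18 myelin genes 13 had a positive interaction, and Cdh1 was the 1 that passed (4 when adjusted over the list alone, median 0.15, camera adjusted p = 3.8e-06, adjusted p = 0.355 with an estimated correlation). Fry made no call for the myelin list (adjusted p = 0.348). Median and mean differed in sign for denervation markers (0.19 and -0.19) and neutrophil genes (0.036 and -0.11), which were not called. All 12 genes with a negative interaction had risen in control nerve, where independent lists would share 2.74, and 7 of the 8 with a positive one had fallen, against 1.40. Simulations without an interaction, in which hardly any gene is called, gave means of 0.11 and 0.07 and at most 2. With the differences of cut nerve on random genes, 30.8% of the genes called negative were risers of control nerve and 22.9% of those called positive its fallers, where 100% and 87.5% were observed. Those simulations with random genes called means of 49.9 negative and 31.7 positive interactions, more than the 12 and 8 observed. Their noise was drawn for each gene separately. The injury and the interaction calls both use the control arrays, and part of the excess may come from them. With these arrays divided between both calls, limma called the interaction for 0 genes in either division (556 and 612 at an unadjusted p under 0.05), so no overlap was left to count. No gene kept its interaction call in all 8 fits with 1 array left out. The count was 0 without mutant cut replicate 1 or either mutant uncut array, 1 without control cut or control uncut replicate 1, 5 and 2 without their replicates 2, and 45 without mutant cut replicate 2, and 0 with an unmoderated statistic. With both cut arrays of higher milk protein signal left out it was 23, and 8 of the 20 genes were among them.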

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

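All 6 tests of explanations in this part were chosen only after the results were seen. Genes and lists stand here because their response to injury differed between genotypes by the interaction test, or because they belong to data that the comparisons above do not use.

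The interaction was called for 20 genes. It was positive for Cdh1 (2.65), Lrrtm4 (2.40), Adam23 (2.33), Lrrn3 (2.05) and Kcnj10 (2.00), and negative for Clca3a2 (-5.66), Krt8 (-3.24), Rgs8 (-2.51), C1ql2 (-2.29), Arg1 (-2.21), Btc (-1.64) and Adamts1 (-1.13), all on the log2 scale. None of the 20 was called in every fit with 1 array left out. The count was 0 without mutant cut replicate 1 or either mutant uncut array, 1 without control cut replicate 1 or control uncut replicate 1, and 45 without mutant cut replicate 2. The lists called by camera had median interactions of 0.15 (myelin), 0.34 (Schwann lineage), -0.42 (trophic factors), -0.76 (repair genes named by the study), 0.13 (cell cycle), 0.064 (lipid-laden macrophages), -0.23 (lymphocytes), -0.38 (mast cells), -0.58 (proteases) and -0.25 (endothelial), and none of these calls held with an estimated correlation (adjusted p from 0.123 to 0.725). Of these lists fry called only the trophic factors and the proteases (adjusted p = 0.0482 and 0.0208). Among 3219 kept probe sets without a single gene symbol, control probe sets not counted, 14 differed between mutant and control cut nerve.

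The first pattern is that 5 of 15 trophic factors and 6 of 10 repair genes named by the study were lower in mutant than in control cut nerve. The camera calls of both lists were lost with an estimated correlation (adjusted p = 0.153 for both). If the mutant segments held a smaller share of Schwann cell RNA, lineage markers would be lower by a similar amount, but their median was 0.16 (SD over genes 0.74) against -0.82 for the repair genes. The lineage markers themselves changed after the cut, 2 rising and 6 falling in control and 4 and 4 in mutant nerve. Their median may thus mix cell state with the share of Schwann cells, so a smaller share is not excluded. Dilution of nerve RNA by other tissue was read from the lineage, endothelial, fibroblast and macrophage lists, whose lowest median was -0.072. Other tissue can carry endothelial, fibroblast and macrophage RNA of its own, so this test cannot decide on dilution. A lower response of these genes in mutant Schwann cells may account for the pattern, a hypothesis found on the same data that stays open.

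The second pattern is that contractile muscle genes were higher in cut than in uncut nerve of both genotypes. More skeletal muscle tissue in the cut segments would make these genes vary together between replicates, and their inter-gene correlation was 0.783. The median over lists was 0.198, but adipocyte (0.823), mast cell (0.689) and neutrophil genes (0.505) also varied together, so that this is consistent with varying amounts of muscle tissue in the segments without being particular to muscle. Over all 11 genes known to rise in denervated muscle, the median exceeded that of the contractile genes by 0.50 in control nerve (SD over genes 1.86, permutation p = 0.0407), but this rests on Ankrd1 and Sln, which were among the highest risers of either genotype. Without them the excess was 0.24 (permutation p = 0.456), and in the mutant it was 0.84 over all 11 and 0.78 without them (permutation p = 0.133 for both). The permutations shuffled genes between both lists. They treat genes that vary together as independent and do not measure the variation between arrays. A higher share of muscle and a change of expression within it cannot be told apart, and injury as a change in the tissue around the nerve stays untested.

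The third pattern is that Krt8, Krt18 and Clca3a2 were high in uncut mutant nerve. RNA of milk-producing epithelium in those pools is a candidate source. The milk protein list holds Csn2, Csn3, Csn1s1, Csn1s2a, Wfdc18, Muc15, Btn1a1 and the transcription factor Elf5. All 8 were higher in both uncut mutant arrays than in both uncut controls, by a median of 5.08 (SD over genes 1.80). Of 7 other glandular epithelium genes, without both keratins, 5 were higher in both uncut mutant arrays, where chance gives 16.7%, but by a median of only 0.62, and Epcam (7.55 and 7.76 against 7.53 and 7.57) and Elf3 (6.64 and 6.94 against 6.53 and 6.62) hardly differed. Such RNA is not a sufficient source of Krt8 and Krt18 in cut nerve, since in the cut arrays with fewer milk transcripts these stood at least 2.70 above the uncut control mean. An effect of genotype on uncut nerve was not tested apart from this and stays open.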

How the results depend on the processing

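The fit without both cut arrays of higher milk protein signal was chosen after seeing the data, and the other settings were planned. Counts of called genes were 4879 and 4348 for injury in control and mutant, 132 and 0 for genotype in cut and uncut nerve and 20 for the interaction. Median centring, a further quantile normalisation and array weights moved none of these counts by over 1.5 times. The interaction gave 33 without a filter or with the mean of a gene's probe sets, 11 with the filter at the 75th percentile and 31 with a trended and robust variance, and the genes that rose in control nerve with a lower interaction, 12 as reported, numbered 22 without a filter and 21 with the mean. An unmoderated statistic gave 2865 for injury in mutant, 0 for genotype in cut nerve and 0 for the interaction. At least 2-fold change left 1511, 1370 and 67 for injury in control, in mutant and genotype in cut nerve. Probe sets as units, of which more are tested, gave 8441, 7240 and 1 for the injury contrasts and genotype in uncut nerve, and the mean of probe sets gave 1 there. With only the 4 arrays compared, genotype gave 31 in cut and 9 in uncut nerve. The added fit gave 2783 for injury in mutant, 55 for genotype in cut nerve (43 shared with the 132), 9 in uncut nerve and 23 for the interaction (8 shared with the 20). Replicate numbers are shared by the groups, and the uncut nerves come from the other side of transected mice, but no label says which pools share mice. Deviations of same-numbered arrays correlated positively between all groups, at 0.02 to 0.34. The replicate difference had the same sign in all groups for 24.2% of genes, where independent signs would give 12.5%. An effect shared by same-numbered arrays is therefore possible, and the main model leaves it in the spread. With the replicate number as a block, injury gave 5544 in control and 4980 in mutant, and genotype gave 174 in cut and 4 in uncut nerve. The interaction gave 25. Only the count of uncut nerve moved by over 1.5 times. In this fit 3 named genes lost their call (Myh2 in mutant injury, Lif in cut nerve and Arg1 in the interaction, limma adjusted p = 0.0547, 0.0616 and 0.0630). So did 5 camera lists: cytokines in control injury, fibroblasts in mutant injury, interferon in cut nerve, Schwann lineage in uncut nerve and lipid-laden macrophages in the interaction (adjusted p = 0.0515, 0.0528, 0.0609, 0.0585 and 0.0531). With 1 array left out, its partner assumed to vary like the other groups, counts ran from 3388 to 4715 and from 2734 to 4260 for injury, 13 to 111 and 0 to 2 for genotype in cut and uncut nerve, and 0 to 45 for the interaction. Signs turned for Jun in uncut nerve (0.020 with the mean of probe sets, -0.10 to 0.021 with 1 array left out) and in cut nerve for Ncam1 (-0.052 to 0.50) and L1cam (-0.30 to 0.064), none of which had been called. With the mean of its probe sets Ncam1 stood higher, at 0.67 in cut nerve (limma adjusted p = 0.069). In uncut nerve the test direction turned with 1 array left out for the Schwann lineage list (medians -0.29 to -0.019, turned without mutant uncut replicate 1) and the mural list (0.034 to 0.28, turned without control uncut replicate 1). Of the camera calls, 55 of 55 were lost with an estimated correlation and 23 with fry. The cause of these changes was not tested, apart from the fewer arrays or more units of some settings.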

Other observations

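The tests, lists and genes in this part were all chosen only after the results were seen. Beyond the lists, single genes differed between mutant and control cut nerve in both directions (limma, Benjamini-Hochberg adjusted over all genes), and they were not tested as groups. Tgfa, a ligand of the EGF receptor, differed by -1.57 (adjusted p = 0.0071), and the retinoic acid enzymes Aldh1a2 and Aldh1a3 by -1.37 and -1.46. The Wnt antagonists Frzb and Wif1 differed by -2.01 and -1.08, the ligand Ndp by -1.09, the receptor Fzd8 by -0.74 and the R-spondin receptor Lgr6 by -1.45, while the antagonist Sostdc1 (1.80, adjusted p = 0.0259) and Dkk3 (0.86) were higher. The GDNF family receptor Gfra2 (-0.88), the HGF receptor Met (-0.76) and the guidance factor Sema3e (-1.34) were lower.

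Further single genes, examples that give no balance of directions, were Cdk5r1 (-1.93), Syt13 (-1.59), Gria1 (-1.40), Celf4 (-1.31), Uchl1 (-1.15), Nrcam (-0.97), Dpysl3 (-0.96), Nes (-0.90), Thy1 (-0.81) and Lingo1 (-0.57), which were lower in mutant cut nerve. Higher were the glutamate receptor Grik3 (1.48, adjusted p = 0.0230), the synaptotagmin Syt4 (1.08, adjusted p = 0.0149), the adhesion gene Chl1 (0.99), the sodium channel Scn8a (0.95, adjusted p = 0.0314) and Atl1 (0.84, adjusted p = 0.0491). The survival gene Bcl2 (-1.02) and the G protein signalling regulator Rgs16 (-1.48) were lower, and the cation channel Trpm3 (1.73), the orphan nuclear receptor Nr4a2 (1.31) and the engulfment receptor Megf10 (1.01) higher. Among the genes of these first paragraphs, only Aldh1a3, Sema3e, Rgs16 and Trpm3 were called in every fit with 1 array left out. All others lost their call in at least 1 of these fits, and Lingo1 and Atl1 in all of them.

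Replicate 1 differed from replicate 2 in the same direction in all 4 groups for 2926 genes, 24.2% of those tested, where independent signs would give 12.5%. The clock gene Per2 was higher in replicate 1 by 1.16, 0.92, 1.72 and 1.39 in control uncut, control cut, mutant uncut and mutant cut nerve, and 10 clock genes in phase with it by medians of 0.56, 0.59, 0.56 and 0.53. In the same order Arntl differed by -1.83, -0.47, -1.72 and -0.52, and 4 genes in antiphase by medians of -0.23, -0.04, 0.17 and 0.03. Glucocorticoid targets differed by medians of 0.45, 0.35, 0.92 and 0.91, with Fkbp5 at 1.72, 1.71, 2.18 and 2.36. Platelet and erythroid genes differed by medians of 0.65, 0.00, 2.41 and 0.38. The interferon-inducible gene Ifi202b differed by 0.12, 0.80, 3.02 and 3.89.

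Of 11 measured muscle denervation genes 7 rose after injury in control and 8 in mutant nerve, with the acetylcholine receptor gene Chrna1 at 4.66 and 5.14 and medians of 1.87 and 2.36. The 17 measured glandular epithelium genes had a median of 2.79 for mutant minus control uncut nerve. They include the 8 genes of the milk protein list and Krt8 and Krt18, which were picked for their values. The 7 others had a median of 0.62. The 8 genes of the milk protein list had array medians of 11.6 and 8.98 in mutant uncut, 5.03 and 5.20 in control uncut, 9.85 and 6.53 in control cut and 5.18 and 7.90 in mutant cut nerve.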
